A study of Homo sapiens with 12 samples.

How the data were processed

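Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in 624Mel, a human melanoma cell line. Per the labels, cells were transfected with an siRNA against MITF (siMITF) or a control siRNA (siCTRL), and 24 hours later received interferon gamma (IFNγ) at 5 ng/mL for 24 hours or no IFNγ. This gave 4 groups of 3 libraries each, 12 in all. Per the labels, 20000 live cells were used per library in place of the kit's 50000, and tagmentation lasted 1 hour in place of 30 minutes. A longer reaction on fewer cells can raise the share of cuts outside open regions, so the share of reads in strong peaks was measured for each library.

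The deposited table gave, for 396823 peaks that were the same in all libraries, a signal per library on a normalized scale, with the interval, the nearest gene and the genomic annotation of each peak. BWA, DESeq2 1.48.2 and GRCh38 are named in the submitters' processing notes, without their roles. The peak caller, read filters and any shift of read ends for the transposase are not given in the sources used here. Coordinates are those of the table, on GRCh38 per the submitters' processing notes. Within each library the deposited signal values were whole multiples of 1 step, so each library's whole reads were recovered by dividing by it, and 100% of the values came out whole within 0.001. The steps equalled median-of-ratios size factors recomputed from the recovered reads. The scale therefore corrects for depth at the median peak, and not for differences in the share of reads that fall in strong peaks.

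The annotation columns of the deposited table were out of step with its signal columns. It lacked 675 intervals, and 320773 annotated rows stood beside another peak's values, starting at row 75376. The 2 parts were therefore joined by interval name. After the join, peak width and mean signal had a Spearman correlation of 0.893 across peaks, against 0.00968 as laid out, and peaks within 1 kb of a transcription start had a median mean signal of 42.7 against 14.7 elsewhere. Reading the rows as laid out would attach most peaks to a wrong gene. The 675 peaks without annotation stayed in the tests, without a gene name. A gene assigned to a distal peak is the nearest one and need not be regulated by it.

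The main test was limma 3.58.1 (limma-trend) in R 4.3.3 on log2(signal + 1), with 4 group means and all 12 libraries in 1 fit, over the 279705 peaks with a mean signal of at least 10. Fold changes are on this log2 scale, which understates the change of weak peaks. The contrasts tested were 5, namely IFNγ in siCTRL cells, IFNγ in siMITF cells, knockdown without IFNγ, knockdown with IFNγ, and the difference of the IFNγ effect between siMITF and siCTRL cells. A peak passed at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a peak comes from limma unless another tool is named. Errors of fold changes are standard errors (SE), and signal is given as mean ± SD over 3 libraries. The labels number the replicates and do not say that they were separate cultures, so p-values of peaks measure the spread between these libraries.

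In all, 15 gene lists were fixed before the data were examined. They were IFNγ primary response, interferon-stimulated ISRE genes, MHC class I, MHC class II, chemokines and immune checkpoints, IFNγ receptor and signalling, melanocytic differentiation and MITF targets, dedifferentiated and invasive state, AP-1 and TEAD factors, NF-kB and inflammatory response, chromatin remodelling factors, lysosome and autophagy, cell cycle, housekeeping, and markers of other cell types. Each was tested as all tested peaks assigned to its genes against all other tested peaks, with limma's camera at a preset correlation of 0.01, adjusted over the 75 pairs of list and contrast. The camera tests were repeated with an estimated correlation. The fry test was run as well, which asks whether a list moves from 0 and does not compare it with other peaks. Peaks of 1 gene are not independent, which the preset correlation does not cover. A gene counted as higher when at least 1 of its peaks rose and none fell.

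Named peaks followed a rule set before the data were examined. For each contrast the rule took the 8 largest rises and the 8 largest falls among passing peaks with a mean of at least 30, no overlap between the 2 groups and a named protein-coding gene. It added up to 3 genes of each list by largest passing fold, and the strongest peak of 16 fixed genes whatever it did. The text gives part of these. A peak in the first set that lay far from its assigned gene on a sex chromosome was left out. Reads from related genes, such as HLA, GBP, IFIT, OAS and CCL families, can be misplaced between copies, and values at these peaks are less certain.

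Recovered reads in peaks ranged from 6.84 M to 54.5 M per library. The peak test was tested on simulated counts drawn from the real means and depths. Single changed peaks were placed only at a mean of at least 30, so recovery at weaker tested peaks was not measured. Differences in the share of reads in strong peaks were not simulated. With 40 peaks per fold size, 4-fold rises were recovered at 100% for IFNγ in siCTRL cells and 2-fold rises at 20%. For the difference of effects the shares for rises were 97.5% at 8-fold, 55% at 4-fold and 0% at 2-fold. A simulated shift of 0.2 (log2) in 1 list was called at an adjusted p of 0.0167, with 0 other lists called. Simulated peaks were drawn independently of each other, so this does not test the preset correlation of the list tests.

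Alternatives were other pseudocounts, filters and thresholds, 2 other scalings, the replicate number as a block, library quality weights, fits on the compared libraries alone, each library left out in turn, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, and for lists promoter peaks only. The library quality weights were uneven. In siCTRL they were 0.243, 0.229 and 8.78 for replicates 1 to 3, and in siMITF + IFNγ 4.69, 0.641 and 0.966. The weighted fit thus rests largely on 1 library in each of these groups. After seeing the data, 4 more were added. They were siCTRL replicate 2 left out with quantile normalization, the share of reads in the 10000 strongest peaks as a model term with and without that library, and reads thinned to the smallest library. On the recovered reads edgeR called 646, 3337, 22682, 12658 and 0 peaks in the 5 contrasts and DESeq2 called 647, 2168, 15361, 7046 and 0. Promoter shares were tested with Fisher's exact test, two-sided, and library measures with exact permutation tests. Fisher's test counts peaks, which are not replicates, so its p describes these peaks and not the spread between libraries. The motif test that was planned was not run, since no genome sequence was used here.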

Results

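Chromatin accessibility was profiled by ATAC-seq in 624Mel melanoma cells, with 3 libraries in each of 4 groups. The groups were control siRNA (siCTRL), control siRNA with IFNγ, MITF siRNA (siMITF), and MITF siRNA with IFNγ. MITF is the master transcription factor of the melanocyte lineage, and IFNγ is a cytokine that activates the genes of antigen presentation. The design asks whether loss of MITF, which moves melanoma cells toward a dedifferentiated state, changes the chromatin response to IFNγ. Values are reads per peak normalized to the median peak of each library, on GRCh38 coordinates.

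Reads in peaks were 19.9, 6.84 and 12.5 M in siCTRL replicates 1 to 3, and 12.6, 11.8 and 14.5 M in siCTRL + IFNγ. The siMITF libraries held 19.1, 15.7 and 18.4 M and the siMITF + IFNγ libraries 54.5, 12 and 21 M. The 10000 strongest peaks took 23.7 ± 6.45% of reads (SD, n = 3) in siCTRL, 25.5 ± 2.98% in siCTRL + IFNγ, 29.8 ± 1.78% in siMITF and 28.1 ± 2.81% in siMITF + IFNγ. siCTRL replicate 2 stood apart, with 16.6% of its reads in these peaks against 29.3% and 25.1% in its group. Between groups, no library measure differed in two-sided exact permutation tests, where 3 against 3 libraries cannot go below p = 0.1 (smallest adjusted p = 0.727 over 16 tests). The first principal component held 41.1% of the variance and had an absolute correlation of 0.976 with the share of reads in the strongest peaks.

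**Figure D1:**
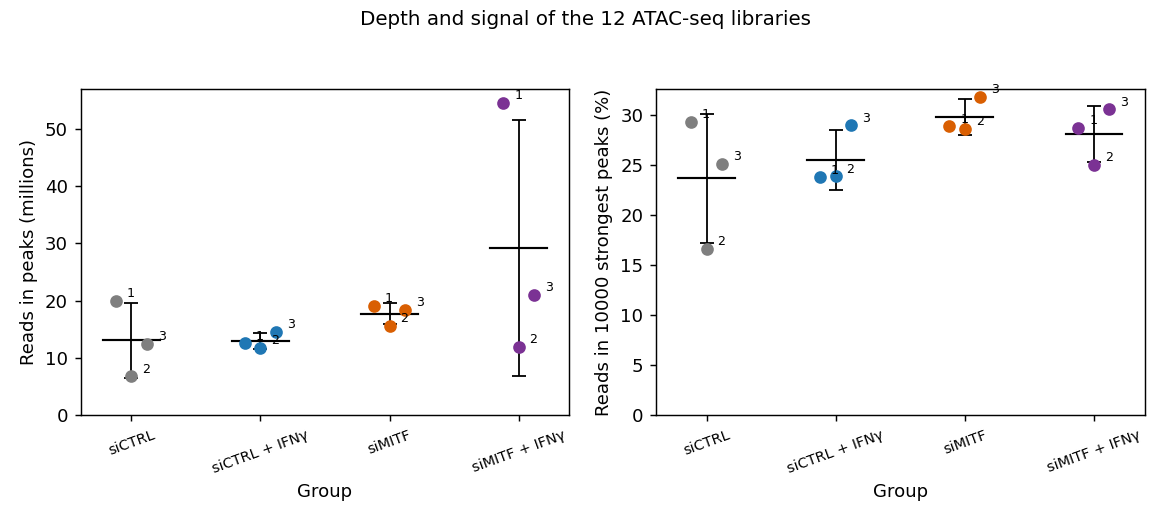
Reads in peaks in M (left) and the percentage of reads in the 10000 strongest peaks (right) for each library, with points for libraries numbered by replicate, a line for the group mean and bars for 1 SD (n = 3). siCTRL replicate 2 has the fewest reads, 6.84 M, and the lowest share in strong peaks, 16.6%.

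In siCTRL cells, IFNγ opened chromatin at interferon target genes. The LAP3 promoter, of a leucine aminopeptidase gene induced by IFNγ, rose from 4.51 ± 2.62 to 48.2 ± 8.87 normalized reads (SD, n = 3), a log2 fold change of 3.28 ± 0.37 (SE). A peak in the promoter of GBP5, a guanylate-binding protein of cell-autonomous immunity, rose from 26.8 ± 7.34 to 239 ± 21.1. Distal peaks nearest CLEC3B and FZD5 rose by 3.15 ± 0.30 and 3.01 ± 0.29, and an intronic peak of SUCLG2 by 2.87 ± 0.35. In all, 730 of 279705 tested peaks passed, 727 higher and 3 lower, each changed at least 2-fold.

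These peaks lay on chromosome 4 at 17580305 to 17580599 for LAP3 (adjusted p = 0.000155) and on chromosome 1 at 89274154 to 89275039 for GBP5 (2.33e-05). The CLEC3B peak was on chromosome 3 at 45061825 to 45062558 (3.52e-05), the FZD5 peak on chromosome 2 at 207772439 to 207772785 (3.52e-05), and the SUCLG2 peak on chromosome 3 at 67489569 to 67490179 (0.000272). In each of them the 3 values with IFNγ lay above the 3 without, which the rule for naming these peaks required. Without siCTRL replicate 1 the count was 21434, without siCTRL replicate 3 it was 380, and without siCTRL + IFNγ replicates 1, 2 and 3 it was 373, 324 and 268. The all-peak median of this contrast was 0.09, and it moved by -0.14 with libraries rescaled to the same total and by -0.10 with quantile normalization.

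The IFNγ primary response genes were higher as a group in siCTRL cells (limma's camera, adjusted p = 2.64e-06, median log2 fold change 0.29). Of their 420 peaks 14 rose and 0 fell, in 10 of 52 genes, with 42 genes not passing. Adjusted over the list alone, 44 peaks were higher and 1 lower. This call held with an estimated correlation (adjusted p = 0.00105). Besides LAP3 and GBP5, a distal peak near FCGR1A, a high-affinity Fc receptor gene, rose by 2.65 ± 0.42, with an adjusted p of 0.0520 without siCTRL + IFNγ replicate 3. Of the IFNγ receptor and signalling genes, an intronic peak of PTPN2, a phosphatase that dampens cytokine signalling, rose by 2.59 ± 0.29 (chromosome 18, 12903877 to 12904601). An intronic peak of IRF1, an interferon-induced transcription factor gene, rose by 1.92 ± 0.29. That list had 4 of 203 peaks higher in 2 of 17 genes and 9 adjusted over the list alone (adjusted p = 0.0457, and adjusted p = 0.969 with an estimated correlation). Its adjusted p was 0.150, 0.116, 0.0819 and 0.137 without siCTRL replicates 2 and 3 and siCTRL + IFNγ replicates 1 and 3, and 0.0948 with quantile normalization.

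Of the interferon-stimulated ISRE genes 3 of 51 had a higher peak, and 9 of 375 peaks were higher adjusted over the list alone (camera adjusted p = 0.0108). The adjusted p was 0.590 with an estimated correlation, 0.0719 without siCTRL replicate 1 and 0.0503 without siCTRL + IFNγ replicate 2. The IFI44 promoter rose by 1.63 ± 0.27 and the IFIT3 promoter by 1.56 ± 0.28, the second with an adjusted p of 0.102 without siCTRL + IFNγ replicate 3. Among chemokines and immune checkpoints 4 of 146 peaks rose (8 adjusted over the list alone, camera adjusted p = 0.279, and 0.0377 without siCTRL replicate 2), among them a peak 4.5 kb from CXCL10, a T-cell chemoattractant, by 2.07 ± 0.31. The MHC class I and class II lists each had 1 peak higher (1 and 2 adjusted over the list alone), with adjusted p of 0.162 and 0.185. The promoter of CD274, the gene of PD-L1, did not pass, at 0.88 ± 0.35, and passed at 1.30 without siCTRL replicate 1 and at 0.68 with the share of reads in strong peaks as a term. The ACTB promoter was at 0.12 ± 0.47, and at -0.16 with quantile normalization.

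In siCTRL cells the melanocytic differentiation list was higher with IFNγ (adjusted p = 0.00259, median 0.27), with 3 of 1037 peaks passing and 4 adjusted over the list alone. With an estimated correlation its adjusted p was 0.969, and it was 0.681 without siCTRL replicate 2, the library with the lowest share of reads in strong peaks, and 0.0725 without siCTRL + IFNγ replicate 3. Its median was 0.49, 0.02 and 0.15 without siCTRL replicate 1, siCTRL replicate 2 and siCTRL + IFNγ replicate 3. The passing peaks were an intronic one of RAB38, a GTPase gene of melanosome transport (2.93 ± 0.37), the promoter of ACP5 (2.22 ± 0.31), and an intronic MITF peak. The last rose by 1.84 ± 0.39, with an adjusted p of 0.369 without siCTRL + IFNγ replicate 3, and was lost in 9 of the 12 fits that left out a library, with libraries rescaled to the same total and with quantile normalization. An intronic peak of TNC, the gene of the matrix protein tenascin C in the dedifferentiated list, rose by 2.32 ± 0.33. That list had 2 of 969 peaks higher, also adjusted over the list alone (adjusted p = 0.960), with a median of 0.10 and a test leaning down. NF-kB and inflammatory genes had 1 of 293 peaks higher and 2 adjusted over the list alone (adjusted p = 0.253). AP-1 and TEAD genes had 0 of 261 in both counts (adjusted p = 0.543).

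In siMITF cells, IFNγ also opened chromatin at interferon target genes. A peak in the IRF1 gene rose from 41.8 ± 3.01 to 330 ± 36.8 normalized reads (SD, n = 3), a log2 fold change of 2.94 ± 0.28 (SE). The LAP3 promoter rose by 3.70 ± 0.37, from 6.43 ± 3.22 to 88.8 ± 2.77, the GBP5 promoter by 3.18 ± 0.27 and the SUCLG2 intronic peak by 3.71 ± 0.35. Intronic peaks of SLC22A15 and CNOT6L rose by 3.12 ± 0.37 and 3.06 ± 0.33. A promoter of CIITA, the master regulator of MHC class II genes, rose from 54.7 ± 13.8 to 206 ± 34.7. Altogether 1771 peaks passed, 1637 higher and 134 lower.

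The IRF1 peak lay in the 3' UTR on chromosome 5 at 132479660 to 132482178 (adjusted p = 1.58e-05), and the CIITA promoter on chromosome 16 at 10878383 to 10879613 (0.000922). The SLC22A15 peak was on chromosome 1 at 116006582 to 116006939 (7.23e-05) and the CNOT6L peak on chromosome 4 at 77734976 to 77735388 (3.67e-05). Without siCTRL replicates 1 and 2 the count was 3048 and 3422, without siMITF replicates 1, 2 and 3 it was 1032, 997 and 951, and without siMITF + IFNγ replicates 1, 2 and 3 it was 704, 1016 and 772. With the share of reads in strong peaks as a model term it was 7558, against 8023 for IFNγ in siCTRL cells. Higher calls made up 92.4%, and 63.6% with that term, 63.0% with that term and siCTRL replicate 2 left out, and 75.9% with quantile normalization and that library left out. They made up 49.0% with only the libraries compared and 48.2% with library quality weights, where falls outnumbered rises, and 78.6% and 75.6% without siCTRL replicates 1 and 2. The all-peak median was -0.06 and moved by 0.14 with libraries rescaled to the same total.

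**Figure D2:**
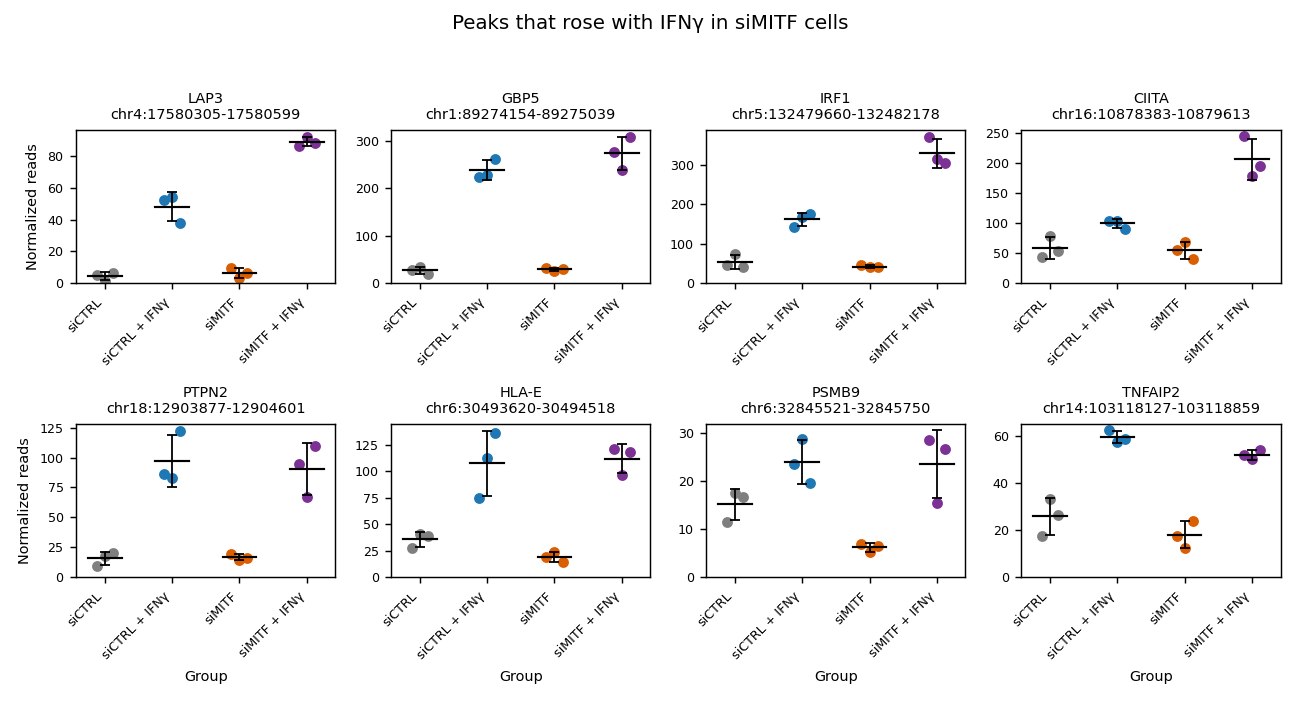
Normalized reads per library at 8 peaks that rose with IFNγ in siMITF cells, 1 panel per gene with the GRCh38 position above it, on linear axes from 0. Points are libraries, lines are group means and bars are 1 SD (n = 3). At IRF1 the siMITF + IFNγ mean is 330 against 162 in siCTRL + IFNγ, and at PTPN2 the means are 90.5 and 97.1.

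Of the IFNγ primary response genes 22 of 52 had a higher peak in siMITF cells, with 43 of 420 peaks higher and 0 lower, and 82 higher adjusted over the list alone. The camera test gave an adjusted p of 2.32e-23, and 1.46e-05 with an estimated correlation (median 0.35). The IFNγ receptor and signalling list had 12 of 203 peaks higher in 3 genes, and 18 adjusted over the list alone (adjusted p = 0.00728). Its adjusted p was 0.969 with an estimated correlation and 0.0586 without siMITF replicate 2. PTPN2 rose by 2.34 ± 0.29.

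Interferon-stimulated ISRE genes had 14 of 375 peaks higher in 14 of 51 genes, 24 higher and 2 lower adjusted over the list alone (adjusted p = 0.000552, and adjusted p = 0.228 with an estimated correlation). The promoter of OAS2, an RNA-sensing synthetase gene, rose from 35.2 ± 6.75 to 174 ± 15.5 (2.29 ± 0.26) and that of IFI27 by 2.32 ± 0.32. MHC class I genes had 4 of 102 peaks higher, 5 adjusted over the list alone (adjusted p = 8.99e-05, and adjusted p = 0.188 with an estimated correlation). Among them a peak at the 3' end of HLA-E rose by 2.51 ± 0.29, and one in PSMB9, an immunoproteasome subunit gene, by 1.72 ± 0.31. Without siMITF + IFNγ replicate 1 the adjusted p of PSMB9 was 0.0968. MHC class II genes had 2 of 113 peaks higher, in CIITA and near LGMN, a lysosomal protease gene (2.61 ± 0.38), and 5 adjusted over the list alone. The adjusted p of that list was 0.000178, and adjusted p = 0.0529 with an estimated correlation.

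Chemokines and immune checkpoints had 5 of 146 peaks higher and 6 adjusted over the list alone (adjusted p = 0.0108, adjusted p = 0.188 with an estimated correlation, and 0.0568 without siMITF replicate 2). The promoter of IDO1, a tryptophan-degrading enzyme gene, rose by 1.81 ± 0.35 and that of CCL8 by 1.52 ± 0.27, with adjusted p of 0.103 without siMITF + IFNγ replicate 3 and 0.0728 without siMITF + IFNγ replicate 1. CXCL10 stood at 1.26 ± 0.31 (adjusted p = 0.0710) and CD274 at 0.50 ± 0.35, and neither passed. The CXCL10 peak passed in 15 of 30 alternative settings, among them without siCTRL replicate 1, without siCTRL replicate 2, with quantile normalization, with the replicate number as a block, with edgeR and with DESeq2. The CD274 peak passed with the share of reads in strong peaks as a term. The melanocytic list had 8 of 1037 peaks higher, also adjusted over the list alone, and a median of -0.15 (adjusted p = 0.162), with ACP5 at 2.82 ± 0.31 and RAB38 at 2.17 ± 0.37. The NF-kB list had 2 of 293 peaks higher (adjusted p = 0.479), near CCL20 (1.67 ± 0.32) and in TNFAIP2 (1.52 ± 0.28). Their adjusted p was 0.0922 without siMITF + IFNγ replicate 1 and 0.0874 without siMITF replicate 2. The dedifferentiated list had 3 of 969 higher (adjusted p = 0.350) and the AP-1 and TEAD list 0 of 261 (adjusted p = 0.769). Adjusted over the list alone, these 3 lists had the same counts. The ACTB promoter stood at -0.22 ± 0.47, and at 0.01 with quantile normalization.

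Among the 134 peaks that fell with IFNγ in siMITF cells, a peak assigned to AHR, the aryl hydrocarbon receptor gene, fell by 1.69 ± 0.32 on the log2 scale, from 116 ± 15.6 to 35.6 ± 6.10 normalized reads. A peak assigned to LGR5, a Wnt-pathway receptor and stem cell marker gene, fell by 1.64 ± 0.28, from 94.9 ± 1.55 to 30.5 ± 8.24. LRRIQ3, LINGO2 and GREB1L peaks fell by 1.84 ± 0.38, 1.67 ± 0.34 and 1.58 ± 0.32. The LGR5 call held without any 1 library, and the highest adjusted p of the others was 0.0789 for AHR, 0.155 for LRRIQ3 and 0.203 for GREB1L without siMITF replicate 3, and 0.133 for LINGO2 without siMITF + IFNγ replicate 1.

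Of the 727 peaks that rose with IFNγ in siCTRL cells, 491 also rose in siMITF cells, or 67.5%, where independent lists would share 4.25. The fold changes of the 2 contrasts use different libraries, but the spread of each peak came from 1 fit of all 12. Peaks with a small spread can therefore pass in both, which the count for independent lists does not allow for. Of the 727, 98.6% had a positive fold change in siMITF cells. Promoters made up 9.63% of the peaks that rose in siCTRL cells and 11.6% of those that rose in siMITF cells, against 14.4% of peaks that did not pass (Fisher's exact test, odds ratios 0.635 and 0.782, adjusted p = 0.000229 and 0.00128). Against peaks matched on mean signal the odds ratios were 0.774 and 0.902, with adjusted p of 0.213 and 0.363. Among the peaks that fell in siMITF cells 5.22% were promoters (odds ratio 0.328, adjusted p = 0.00128).

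For the knockdown, the MITF locus itself was examined first. An siRNA acts on the mRNA, so accessibility at the gene does not check the knockdown. The 62 tested MITF peaks together held 6246, 2130 and 3690 normalized reads in siCTRL replicates 1 to 3 and 5603, 5450 and 7437 in siMITF. They held 4434, 4342 and 6797 in siCTRL + IFNγ, and 5234, 4010 and 6101 in siMITF + IFNγ. Of the 62 peaks, 8 rose with knockdown without IFNγ, 1 rose with knockdown with IFNγ, and 0 fell in either. The strongest, at a promoter, stood at 0.87 ± 0.46 and did not pass, and passed at 1.27 without siCTRL replicate 1.

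Without IFNγ, MITF knockdown opened many distal and intronic peaks. An intronic peak of UNC5C, a netrin receptor gene, rose from 11 ± 6.51 to 129 ± 18.9 normalized reads (SD, n = 3), a log2 fold change of 3.55 ± 0.34 (SE). Peaks near PANK3 and CSNK1G3 rose by 3.09 ± 0.27 and 3.08 ± 0.41, and the AHR peak by 3.07 ± 0.32. Falls were seen at an intronic peak of B3GALNT2 (by 2.85 ± 0.43), and near ZNF439 (by 2.76 ± 0.46) and HAAO. The HAAO peak fell by 2.59 ± 0.35, from 185 ± 90.6 to 27.3 ± 5.00. Peaks of PIR and SOX5, the second a transcription factor gene related to SOX10, fell by 2.44 ± 0.41 and 2.37 ± 0.37. In all, 22910 peaks passed, 18771 higher and 4139 lower, so 81.9% were higher.

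The UNC5C peak lay on chromosome 4 at 95506265 to 95506596 (adjusted p = 3.06e-05) and the AHR peak on chromosome 7 at 17090831 to 17091385 (5.77e-05). The HAAO peak lay on chromosome 2 at 42882609 to 42883465 (0.000199), the PIR peak on chromosome X at 15495802 to 15496280 (0.00102) and the SOX5 peak on chromosome 12 at 23589663 to 23590213 (0.000580). The split of calls moved with the scaling, with 53.9% of 22351 calls higher after rescaling to the same total, 67.9% of 23824 after quantile normalization and 54.0% of 29844 with the share of reads in strong peaks as a term. With siCTRL replicate 2 left out as well, quantile normalization gave 60.7% of 22777 and the term 54.4% of 32261. The all-peak median was 0.09 and moved by -0.34 with rescaling and by -0.12 with quantile normalization. Without siCTRL replicate 1 the count was 86846, without siCTRL replicate 3 it was 8963, and without siMITF replicates 1, 2 and 3 it was 12683, 11733 and 6739.

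**Figure D3:**
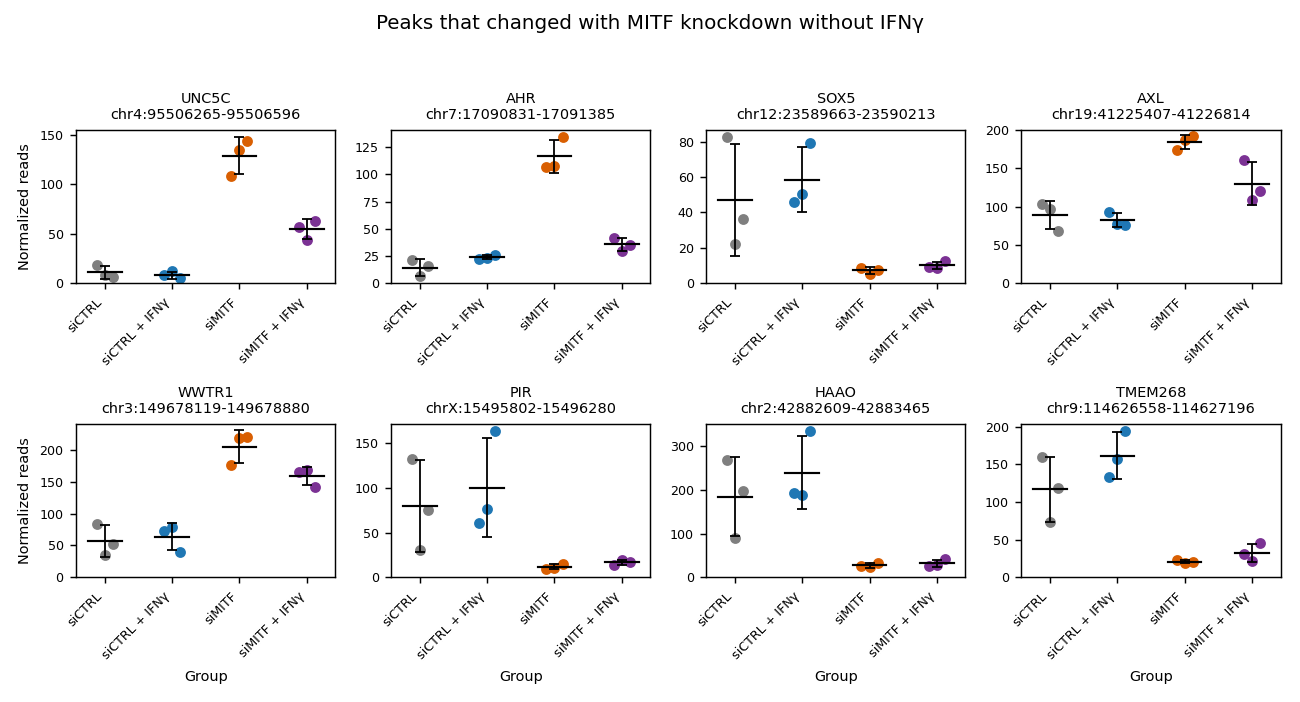
Normalized reads per library at 8 peaks that changed with MITF knockdown without IFNγ, 1 panel per gene with the GRCh38 position above it, on linear axes from 0. Points are libraries, lines are group means and bars are 1 SD (n = 3). The AHR peak has means of 14.3, 23.6, 116 and 35.6 in the order drawn, and the HAAO peak means of 185, 239, 27.3 and 31.9.

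Of the 63 genes of the dedifferentiated and invasive list, 40 had a higher peak and none lower, 2 the reverse, 4 both and 17 did not pass. Over all tested peaks 18771 of 279705 rose and 4139 fell. A gene with many peaks is likelier to hold a passing one. Gene counts alone, here and in the lists that follow, therefore do not set a list apart. Of the peaks of this list, 160 of 969 rose and 7 fell, and 207 and 10 adjusted over the list alone. Examples were PDGFC, a growth factor gene, by 2.66 ± 0.41, POSTN, the gene of the matrix protein periostin, from 32.7 ± 19.3 to 168 ± 33.0, and RUNX1 by 2.67 ± 0.60. RUNX1 had an adjusted p of 0.0747 without siMITF replicate 3. The promoter of AXL, a receptor kinase gene of invasive melanoma cells, rose from 89.5 ± 18.3 to 185 ± 9.41 (1.06 ± 0.28, adjusted p = 0.0217). The AXL call was lost in 9 of 30 alternative settings, among them without siCTRL replicate 3 (adjusted p = 0.130), without siMITF replicates 1, 2 and 3, with libraries rescaled to the same total (0.71) and with quantile normalization (0.47, log2). The strongest peak of NGFR, another gene of this list, did not pass in the main fit or in any alternative. Its log2 fold change was 0.24 to 0.55 over left-out libraries, and -0.26 at its lowest over all settings. The list passed with camera (adjusted p = 0.00728, median 0.28), and its adjusted p was 0.777 with an estimated correlation. Its median was -0.05 with libraries rescaled to the same total. In this contrast siCTRL libraries had 23.7% and siMITF libraries 29.8% of reads in the strongest peaks.

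AP-1 and TEAD factor genes had 23 of 261 peaks higher and 0 lower in 9 of 24 genes (26 and 0 adjusted over the list alone), and NF-kB and inflammatory genes 26 of 293 higher and 4 lower (29 and 4). The counts in brackets are adjusted over the list alone. Neither list passed as a group (adjusted p = 0.0566 and 0.0510). AP-1 and TEAD genes were at 0.0203 without siCTRL replicate 1 and 0.0291 without siMITF replicate 2. NF-kB genes were at 0.0314, 0.0346 and 0.0485 without siCTRL replicate 1, siMITF replicate 3 and siMITF + IFNγ replicate 1. Intronic peaks of WWTR1 and YAP1, the genes of the TEAD coactivators TAZ and YAP, rose by 1.92 ± 0.32 and 1.82 ± 0.34, and one of ATF3, an AP-1 family gene, by 1.60 ± 0.30. Peaks near CXCL8, the gene of interleukin 8, and CD83 rose by 2.20 ± 0.38 and 1.73 ± 0.28, and an intronic one of TNFAIP8 by 1.76 ± 0.29. Of the melanocytic list 77 of 1037 peaks rose and 23 fell (89 and 28 adjusted over the list alone), with 18 of 54 genes higher, 9 lower, 7 both and 20 not passing (adjusted p = 0.461, and 0.0314 without siCTRL replicate 1). GPM6B, MITF and KIT peaks rose by 2.51 ± 0.39, 2.47 ± 0.46 and 2.05 ± 0.40. The strongest peaks of MLANA, TYR and PMEL, genes of melanosome proteins and pigment synthesis, stood at -0.03 ± 0.37, 0.72 ± 0.43 and 0.75 ± 0.48 and did not pass. MLANA passed as lower with quantile normalization (-0.59) and with the share of reads in strong peaks as a term (-0.78), and TYR and PMEL passed as higher without siCTRL replicate 1 (1.22 and 1.17). The promoter of SOX10, a neural crest factor, was at 0.19 ± 0.40, and -0.56 with quantile normalization, where it passed. The ACTB promoter stood at 0.50 ± 0.47, and -0.24 with quantile normalization, where it passed.

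The IFNγ primary response list was lower in siMITF than in siCTRL cells before IFNγ (adjusted p = 0.0142, and adjusted p = 0.0285 with an estimated correlation), with a median of -0.15 and a mean of -0.08. The median was -0.09 without siCTRL replicate 2, -0.48 with libraries rescaled to the same total and 0.03 with promoter peaks only. Yet its passing peaks went both ways, 14 higher and 12 lower, and 9 and 9 adjusted over the list alone. The adjusted p was 0.206 with the share of reads in strong peaks as a term and 0.0867 with quantile normalization and siCTRL replicate 2 left out, so the list no longer passed in either. MHC class I genes had 6 of 102 peaks lower and 1 higher, 7 and 3 adjusted over the list alone (adjusted p = 0.159). Peaks of HLA-C, HLA-B and PSMB9 fell by 1.59 ± 0.43, 1.38 ± 0.36 and 1.14 ± 0.31. Each of these calls was lost in at least 1 fit that left out a library, with adjusted p up to 0.0934 without siMITF replicate 1, 0.102 without siCTRL replicate 2 and 0.104 without siCTRL replicate 3. All 3 calls were also lost with the share of reads in strong peaks as a term and with quantile normalization and siCTRL replicate 2 left out, and over all settings the smallest falls were -0.95, -0.93 and -0.69. ISRE genes had 19 of 375 peaks higher and 6 lower (13 and 2 adjusted over the list alone, adjusted p = 0.850), with the OAS1 promoter at 2.44 ± 0.42 and a distal peak of IFI44 at 1.87 ± 0.27. Chemokines and checkpoints had 14 of 146 higher and 2 lower (18 and 5 adjusted over the list alone, adjusted p = 0.850), MHC class II genes 4 of 113 higher and 2 lower (1 and 2, adjusted p = 0.641), and receptor and signalling genes 9 of 203 higher and 6 lower (9 and 6, adjusted p = 0.860). An intergenic peak near IFNGR1, the IFNγ receptor gene, rose by 2.32 ± 0.43. In the ISRE, MHC class II, chemokine and receptor lists the median was above 0 while the test leaned down.

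With IFNγ present, knockdown changed peaks in both directions. The UNC5C peak rose by 2.66 ± 0.34. A peak of GMDS rose from 14.8 ± 5.18 to 85 ± 8.56 normalized reads, and one of RIN3 by 2.32 ± 0.30. ZNF439 and HAAO peaks fell by 3.11 ± 0.46 and 2.84 ± 0.35, and an RGMB peak fell by 2.77 ± 0.40. An intronic peak of CDH1, the gene of E-cadherin, fell by 2.62 ± 0.34, from 134 ± 49.6 to 20.2 ± 3.13 normalized reads (SD, n = 3; chromosome 16, 68784046 to 68784967, adjusted p = 0.00114). In all, 5616 peaks passed, 2338 higher and 3278 lower. Without siCTRL replicates 1 and 2 the count was 13096 and 15010, without siCTRL + IFNγ replicates 1, 2 and 3 it was 3233, 2056 and 934, and without siMITF + IFNγ replicates 1, 2 and 3 it was 1072, 1605 and 2305. The share of higher calls was 41.6%, and it was 30.9% of 42339 calls with the share of reads in strong peaks as a term. It was 28.0% without siMITF + IFNγ replicate 3, and rises were the majority without siCTRL + IFNγ replicate 3 (57.3%), with library quality weights (56.8%) and with a mean of at least 50 (56.0%). More peaks passed with IFNγ than without it with that term (42339 against 29844, and 43681 against 32261 with siCTRL replicate 2 left out), with only the libraries compared (17430 against 8905), and with quantile normalization and siCTRL replicate 2 left out (27532 against 22777).

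Of the 54 genes of the melanocytic differentiation list, 18 had a lower peak, 1 a higher, 4 both and 31 did not pass, with 25 of 1037 peaks lower and 6 higher (32 and 8 adjusted over the list alone). Over all tested peaks 3278 of 279705 fell and 2338 rose in this contrast. Beside CDH1, a peak of PIR fell by 2.40 ± 0.41 and the promoter of IVNS1ABP fell from 20 ± 3.61 to 3.45 ± 3.51. The list passed with camera (adjusted p = 0.00728, median -0.10), and its adjusted p was 0.969 with an estimated correlation, 0.150 without siCTRL + IFNγ replicate 3 and 0.126 without siMITF + IFNγ replicate 2. Its median was -0.03 and -0.05 without these libraries, and ran from -0.25 to -0.03 over all settings. The call was also lost with library quality weights. MLANA stood at -0.56 ± 0.37, TYR at 0.01 ± 0.43 and PMEL at 0.15 ± 0.48, none passing. MLANA passed as lower with quantile normalization (-0.68) and with the share of reads in strong peaks as a term (-0.88). TYR was at -0.34 with the share of reads in strong peaks as a term, where it passed. The dedifferentiated list was higher (adjusted p = 0.00384, median 0.19, and adjusted p = 0.700 with an estimated correlation), with 29 of 969 peaks higher and 9 lower, and 50 and 18 adjusted over the list alone. The promoters of ANKRD1, a YAP target gene, and TGFBI, a matrix protein gene, rose by 1.84 ± 0.25 and 1.83 ± 0.31. AXL stood at 0.64 ± 0.28 and did not pass, and passed with the share of reads in strong peaks as a term.

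Interferon lists did not differ as groups between siMITF and siCTRL cells under IFNγ. The primary response list had 1 of 420 peaks higher and 5 lower, 1 and 4 adjusted over the list alone (adjusted p = 0.717). Peaks of IRF2 and JAK2 fell by 1.78 ± 0.38 and 1.76 ± 0.41, with adjusted p of 0.136 and 0.179 without siCTRL + IFNγ replicate 3. ISRE genes had 3 of 375 higher and 5 lower (6 and 8, adjusted p = 0.773), MHC class I genes 0 of 102 and 1 (0 and 0, adjusted p = 0.914), and MHC class II genes 0 of 113 and 1 (0 and 1, adjusted p = 0.402). Chemokines and checkpoints had 3 of 146 higher and 0 lower (3 and 0, adjusted p = 0.627), and receptor and signalling genes 2 of 203 and 5 (5 and 8, adjusted p = 0.850). The counts in brackets are adjusted over the list alone. For MHC class I the median was 0.01 and the test leaned down. AP-1 and TEAD genes had 4 of 261 higher and 1 lower (7 and 1, adjusted p = 0.159), led by WWTR1 at 1.64 ± 0.29, and NF-kB genes 2 of 293 and 2 (2 and 2, adjusted p = 0.543).

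Knockdown calls in the absence and presence of IFNγ overlapped, though they use different libraries. Of peaks that rose without IFNγ, 1929 of 18771 also rose with it, where independent lists would share 157, and of those that fell 985 of 4139 also fell, against 48.5. Peaks that rose with knockdown were less often promoters, at 8.38% without IFNγ and 8.86% with it, against 14.8% and 14.5% of peaks that did not pass (Fisher's exact test, odds ratios 0.525 and 0.574, adjusted p = 6.57e-148 and 7.73e-16). These p-values count peaks and do not measure the spread between libraries. Among peaks that fell, promoters made up 10.9% without IFNγ (odds ratio 0.705, and 1.10 against peaks matched on mean signal, adjusted p = 0.228) and 6.75% with IFNγ (odds ratio 0.427).

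The difference of the IFNγ effect between siMITF and siCTRL cells asks the question of the design at each peak. No single peak passed (limma, 0 of 279705, smallest adjusted p = 0.579), with 24050 at an unadjusted p under 0.05, and edgeR and DESeq2 also called 0. Of simulated rises at peaks with a mean of at least 30, those of 4-fold were found in 55% of cases and those of 2-fold in 0%. Recovery at weaker peaks was not measured. The strongest peaks of CXCL10 and CIITA had differences of -0.80 ± 0.44 and -0.18 ± 0.49, with CIITA at 0.17 under quantile normalization. Without siCTRL replicate 1 the count was 11345, with 1231 higher and 10114 lower, and the other 11 fits that left out a library gave 0. The all-peak median of -0.15 moved by 0.27 with libraries rescaled to the same total and by 0.15 with quantile normalization.

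As a group, the IFNγ primary response genes gained more accessibility with IFNγ in siMITF than in siCTRL cells (camera adjusted p = 0.00235). They started lower in siMITF cells (mean -0.08 without IFNγ) and did not differ as a group with IFNγ (mean 0.04, camera adjusted p = 0.717). The median difference over their 420 peaks was 0.08 and the mean 0.11 (log2), where all peaks had a median of -0.15, and 0 peaks passed, also adjusted over the list alone. The list median was 0.14 without siCTRL replicate 1, 0.05 without siMITF + IFNγ replicate 2, 0.15 without siMITF + IFNγ replicate 3, 0.35 with libraries rescaled to the same total and 0.23 with quantile normalization. The call held with an estimated correlation (adjusted p = 0.00976). The melanocytic list went the other way (adjusted p = 0.00147, median -0.42 over 1037 peaks). Its adjusted p was 0.969 with an estimated correlation and 0.0797 without siCTRL replicate 2. Its median was -0.69 and -0.16 without siCTRL replicates 1 and 2, -0.15 with libraries rescaled to the same total and -0.23 with quantile normalization. The ISRE, MHC class I, MHC class II, chemokine and receptor lists had adjusted p of 0.641, 0.149, 0.162, 0.526 and 0.742, with medians from -0.20 to -0.06 and tests leaning up. For MHC class I and class II the means were 0.03 and 0.02, and MHC class I was at 0.0463 without siCTRL replicate 2. The dedifferentiated, AP-1 and NF-kB lists had 0.576, 0.501 and 0.159.

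Over the 2921 peaks that rose with IFNγ averaged over both siRNAs, the median log2 fold change was 1.15 in siCTRL and 1.34 in siMITF cells. The median difference was 0.20, and 63.6% of these peaks had the larger change in siMITF cells. It was -0.41 without siCTRL replicate 1, and -0.04 with the share of reads in strong peaks as a model term.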

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

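The list tests and the random splits were planned, and the share of reads in strong peaks as a model term was added after seeing the results. The IFNγ primary response list was marked for a closer look because its IFNγ effect differed between siMITF and siCTRL cells (adjusted p = 0.00235). In 100 of the possible splits of the libraries, 1, the real one, gave a result as large. Its unadjusted camera p was 0.000219, against a smallest other p of 0.000338. The margin was narrow and not every split was run. Other splits mix the 2 siRNAs, so the knockdown effect adds to their spread. A chance difference between libraries was therefore not excluded. With the share of reads in strong peaks as a term and siCTRL replicate 2 left out, the camera adjusted p was 0.00156. That argues against different signal to noise of the libraries as the whole reason. It does not exclude it, since 1 linear term chosen after seeing the results need not remove all of its effect. A lower level of the list in siMITF cells before IFNγ cannot be told apart, since that difference had an adjusted p of 0.206 with the same term. In the main fit the list was lower in siMITF cells without IFNγ (mean -0.08, camera adjusted p = 0.0142). With IFNγ it did not differ as a group (mean 0.04, camera adjusted p = 0.717). The difference of effects is the second minus the first, so in that fit the larger part of its mean of 0.11 lay in the level before IFNγ. Per library, the median change of the list beyond all peaks was 0.22, 0.26 and 0.14 in siCTRL + IFNγ and 0.40, 0.52 and 0.36 in siMITF + IFNγ. The list medians themselves were 0.29, 0.34 and 0.30 against 0.37, 0.44 and 0.35. Much of the gap thus lay in the all-peak medians, 0.08, 0.08 and 0.16 against -0.03, -0.08 and -0.01. The 3 values of a group share 1 untreated mean, so they are not independent of each other.

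The melanocytic differentiation list was marked because it differed the other way (adjusted p = 0.00147). Of 100 splits 24 gave a result as large, with a smallest other p of 4.20e-08, so a chance difference between libraries could not be excluded.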

How the results depend on the processing

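Alternatives chosen after seeing the results were those with siCTRL replicate 2 left out together with another change, the share of reads in strong peaks as a term, and thinned reads. Of simulated rises in the difference of effect, all at peaks with a mean of at least 30, 0% were found at 2-fold, 55% at 4-fold and 97.5% at 8-fold. Depth and the number of replicates were not varied there. A part of the peaks named by the rule, 157, was followed over the settings. Of these 122 passed, and 69 of the 122 passed the same way in every setting run, while 3 of the 157 passed in a setting with the sign opposite to their value. Others that did not pass changed sign without passing, among them ACTB, GAPDH, CIITA, PMEL and MITF peaks. With thinned reads 26 of the 122 calls were lost. Among them were those at IRF1 and ACP5 for IFNγ in siCTRL cells, at AHR, CCL20 and PSMB9 for IFNγ in siMITF cells, at RUNX1, AXL, HLA-B, HLA-C and PSMB9 for knockdown without IFNγ, and at IVNS1ABP and WWTR1 for knockdown with IFNγ. The cause was not tested unless given. Counts with library quality weights rest largely on replicate 3 for the siCTRL group (weight 8.78, against 0.243 and 0.229).

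The count for IFNγ in siCTRL cells (730) was 331 at an adjusted p under 0.01, 236 with a mean of at least 50, 1108 with quantile normalization, 1538 with that and siCTRL replicate 2 left out, 45809 with library quality weights and 196 with only the libraries compared. It was 8023 with the share of reads in strong peaks as a term, 6934 with that and siCTRL replicate 2 left out, 336 with thinned reads and 1193 with edgeR and replicate block. Leaving out each library gave 268 to 21434.

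The count for IFNγ in siMITF cells (1771) was 895 at an adjusted p under 0.01, 350 with a mean of at least 50, 17499 with library quality weights and 7895 with only the libraries compared. It was 4704 with quantile normalization and siCTRL replicate 2 left out, 7558 with the share term, 7778 with that and siCTRL replicate 2 left out, 1076 with thinned reads, 3337 with edgeR and 5276 with edgeR and replicate block. Leaving out each library gave 704 to 3422.

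The count for knockdown without IFNγ (22910) was 7374 at an adjusted p under 0.01, 9306 with a mean of at least 50, 131712 with library quality weights, 8905 with only the libraries compared, 13204 with thinned reads and 38518 with edgeR and replicate block. Leaving out each library gave 6739 to 86846.

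The count for knockdown with IFNγ (5616) was 1170 at an adjusted p under 0.01, 1954 with a mean of at least 50, 10633 with libraries rescaled to the same total, 12305 with quantile normalization and 27532 with that and siCTRL replicate 2 left out. It was 40652 with library quality weights, 17430 with only the libraries compared, 42339 with the share term, 43681 with that and siCTRL replicate 2 left out, 12658 with edgeR and 18716 with edgeR and replicate block. Leaving out each library gave 934 to 15010.

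The count for the difference of the IFNγ effect (0) was 31177 with library quality weights, 246 with the share term and 648 with that and siCTRL replicate 2 left out. Of these calls 21453, 225 and 613 were lower. Leaving out each library gave 0 to 11345. The IFNγ primary response list passed in every camera setting run, with an adjusted p of 0.000735 to 0.00706 over left-out libraries. The melanocytic list (adjusted p = 0.00147) was at 0.969 with an estimated correlation, and 0.0867 with quantile normalization and siCTRL replicate 2 left out, and at 5.95e-05 to 0.0797 over left-out libraries. The fry test, which asks whether the melanocytic list moved from 0 and not whether it differed from other peaks, gave 0.449.

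With the replicate block the counts were 1555, 2397, 40539, 10642 and 0 in the order above. Of 18 same-numbered pairs of libraries 11 had a correlation over 0.1, from -0.33 to 0.48, and 2 of 12 libraries correlated best with their own number in every other group, so the libraries were not treated as paired.

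Direction also changed in the following cases. The promoter odds ratio of peaks that fell with knockdown without IFNγ (0.705) was 1.10 against peaks matched on mean signal. The median difference of the IFNγ effect at peaks that rose on average (0.20) was -0.41 to 0.293 over left-out libraries, -0.41 without siCTRL replicate 1, -0.0365 with the share of reads in the top 10000 peaks as a term, and -0.0632 with that and siCTRL replicate 2 left out. For knockdown without IFNγ, the SOX10 peak (0.19) was at -0.56 with quantile normalization, -0.33 with that and siCTRL replicate 2 left out and -0.32 with the share term and that library left out, and the ACTB peak (0.50) at -0.24 and -0.25 in the first 2 of these. The median of the IFNγ primary response list for knockdown without IFNγ (-0.15) was 0.03 with promoter peaks only, and that of the dedifferentiated list (0.28) was -0.05 with libraries rescaled to the same total. The TYR peak for knockdown with IFNγ (0.01) was at -0.34 with the share term. The share of higher calls for IFNγ in siMITF cells (92.4%) was 49.0% with only the libraries compared and 48.2% with library quality weights, and that for knockdown with IFNγ (41.6%) was 57.3% without siCTRL + IFNγ replicate 3, 56.8% with library quality weights and 56.0% with a mean of at least 50. IFNγ had fewer calls in siMITF than in siCTRL cells without siCTRL replicate 1 (3048 against 21434), with library quality weights (17499 against 45809) and with the share term (7558 against 8023). Knockdown with IFNγ had more calls than without it with the share term, with only the libraries compared, with quantile normalization and siCTRL replicate 2 left out, and with the share term and that library left out.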

Other observations

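The tests in this part on peaks opened by the knockdown, on thinned reads and on the share of reads in strong peaks were chosen after seeing the results. Knockdown without IFNγ also raised peaks of genes outside the interferon and melanoma lists. Over all tested peaks 18771 of 279705 rose and 4139 fell in this contrast, so rises in the lists below are not particular to them. None of these lists passed as a group in the main fit. Peaks of CDK6, a cell cycle kinase gene, and SMARCA2, a chromatin remodelling ATPase gene, rose by 1.99 ± 0.27 and 1.95 ± 0.34 (log2, SE, n = 3). A peak of LAMP2, a lysosomal membrane protein gene, rose by 2.78 ± 0.60, with an adjusted p of 0.0524 without siMITF replicate 3. Of chromatin remodelling factors 29 of 435 peaks rose and 6 fell (29 and 6 adjusted over the list alone, adjusted p = 0.627), and of cell cycle genes 13 of 204 rose and 2 fell (8 and 1, adjusted p = 0.0746, and 0.0322 and 0.0318 without siCTRL replicate 1 and siMITF replicate 2). Lysosome and autophagy genes had 14 of 254 peaks higher and 7 lower (14 and 7, adjusted p = 0.482), housekeeping genes 9 of 138 and 3 (12 and 3, adjusted p = 0.627), and markers of other cell types 10 of 229 and 4 (9 and 4, adjusted p = 0.889). For the last list the median was 0.12 and the test leaned down.

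With IFNγ present, knockdown lowered 7 of 254 lysosome and autophagy peaks and raised 0 (8 and 1 adjusted over the list alone, adjusted p = 0.254). A peak of ATP6V0A1, a proton pump gene, fell by 1.85 ± 0.32. Chromatin factors had 1 peak higher and 3 lower (1 and 2, adjusted p = 0.769), cell cycle genes 2 and 0 (2 and 0, 0.461), housekeeping genes 1 and 0 (1 and 0, 0.627) and markers of other cell types 0 and 4 (0 and 4, 0.482).

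For IFNγ in siCTRL cells, lysosome genes had 2 peaks higher (4 adjusted over the list alone, adjusted p = 0.114, and 0.0322 without siCTRL replicate 1) and housekeeping genes 1 (1 adjusted over the list alone, adjusted p = 0.863, median 0.07 with the test leaning down). Chromatin, cell cycle and other-cell lists had 0 (adjusted p = 0.863, 0.965 and 0.850). For IFNγ in siMITF cells, housekeeping genes and markers of other cell types had 1 peak higher each (1 and 2 adjusted over the list alone, adjusted p = 0.773 and 0.769). Chromatin, lysosome and cell cycle lists had 0 (adjusted p = 0.860, 0.404 and 0.110, the last 0.0307 without siMITF replicate 2). For the difference of the effects all had 0, with adjusted p of 0.850 for chromatin, 0.0615 for lysosome, 0.289 for cell cycle, 0.889 for housekeeping and 0.717 for other cells. The lysosome list was at 0.0314, 0.0291 and 0.0255 without siCTRL replicate 1, siMITF replicate 2 and siMITF + IFNγ replicate 1.

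A hypothesis from these data is that IFNγ partly closes chromatin that MITF loss has opened, as at AHR. To test it on separate libraries, the 1000 peaks most raised by the knockdown were chosen on 1 siMITF and 1 siCTRL library and measured on the others, in 9 choices, where the median IFNγ effect in siMITF cells was -0.54 (from -0.64 to -0.39) against -0.01 at peaks matched on signal, and 0.06 in siCTRL cells. After quantile normalization the highest of 9 medians beyond matched peaks was -0.37, which argues against different signal to noise of the libraries as the whole reason. It does not exclude it, since the share of reads in strong peaks was not used as a term here. All 9 choices also used the same siMITF + IFNγ libraries. A weaker knockdown in the libraries with IFNγ cannot be told apart, since at the peaks most lowered by the knockdown the median change beyond matched peaks without quantile normalization was 0.0882 (from -0.06 to 0.15).

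More peaks passed with IFNγ in siMITF than in siCTRL cells with all libraries in (2.43 times), but this turned without siCTRL replicate 1 (0.142 times, with 2395 rises against 19298) and with library quality weights (0.382 times, with 8440 rises against 30959). In the weighted fit siCTRL replicate 3 had a weight of 8.78, against 0.243 and 0.229 for siCTRL replicates 1 and 2. The ratio was 4.17 and 4.14 times without siCTRL replicates 2 and 3, 4.06, 4.53 and 6.49 without siCTRL + IFNγ replicates 1, 2 and 3, 1.62 and 1.45 without siMITF replicates 2 and 3, and 1.39 and 1.28 without siMITF + IFNγ replicates 1 and 3. Thinning the reads argues against fewer reads in the siCTRL libraries as the whole reason, since it gave 3.20 times. Whether the different signal to noise of the libraries accounts for it stays open. The ratio was 0.942 with the share of reads in strong peaks as a term and 1.12 with that and siCTRL replicate 2 left out. With quantile normalization it was 1.73, and 3.06 with that and siCTRL replicate 2 left out. It was 40.3 with only the libraries compared, 5.17 with edgeR and 3.35 with DESeq2.

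Splits of the libraries were compared with the real grouping. For the 4 simple contrasts 10 splits are too few, and 1, the real one, gave 730, 1771, 22910 and 5616 peaks against a highest other count of 0. For the difference of the IFNγ effect all 100 splits reached the real count of 0, and the highest other was 30775, with labels exchanged in the IFNγ libraries, which measures the knockdown effect.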
